A study of Drosophila melanogaster with 3 samples.

How the data were processed

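ChIP-seq peaks of GFP-tagged Hr3 were analysed for 3 biological replicates of whole embryos of 0 to 24 h. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The aligner, the peak caller, its settings and the reproducibility threshold are not given in the sources used here. A control library is named in the labels' texts as an input of the authors' signal tracks; it was not analysed here, so peaks that would arise without the tagged protein were not separated from the others.

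The deposited signal value of each peak, which is never negative, is the strength given by the authors' peak caller, and its scale differs between lists. The deposited -log10 q value has a maximum shared by 5643 peaks of the pooled list, so peaks were ranked by signal. Per the text files deposited with the samples, the authors called relaxed peaks in each replicate and on the pooled alignments, and derived the reproducible list by the irreproducible discovery rate (IDR) on the dm3 and dm6 assemblies. Coordinates are on dm6, 1-based. The dm3 lists served for counts and sharing alone, as a dm3 genome was not used here.

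The dm6 genome sequence and the Ensembl release 115 annotation (BDGP6.54, the same assembly) were used with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Transposable elements were left out of the annotation. A summit within 500 bp of a TSS of any transcript was a promoter summit; the rest were assigned in the order coding exon, UTR, other exon, intron and intergenic. Promoter shares were set against 1000 random placements on the same arms, and arms were tested by two-sided exact binomial tests. Sequence elements were searched on both strands within 100 bp of summits and of points 500 bp away, and tested by the exact McNemar test on discordant peaks. Signals were compared by 100000 permutations across peaks. For 24 gene lists, two-sided Fisher's exact tests compared members with all other of the 13945 protein-coding genes. A summit within 500 bp of the TSSs of several genes was counted for each of them. The tests of arms, sequence elements and gene lists were adjusted by Benjamini-Hochberg within each family, the 8-base sequences by Bonferroni, and the signal comparisons were left unadjusted, all with a threshold of 0.05. Intervals are 95% exact binomial, or percentile bootstrap with 1000 draws, and cover counting error only. Values per replicate come from each replicate's 5357 strongest peaks, or, for single peaks, from its relaxed peak at the reproducible summit. Peaks and genes are not independent replicates, so p-values across them describe these lists; with 3 replicates of 1 group no test between samples was made.

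Elements, lists, tests and alternatives were fixed before the data were examined, except those stated below to have been added or chosen later. Named genes followed a rule fixed likewise: all members of the ecdysone cascade and nuclear receptor lists with values for the 12 bound genes whose strongest peak in the gene or within 1 kb ranks highest, the nearest genes of the 10 strongest peaks seen in all 3 replicates, the 8 strongest peaks with a RORE within 50 bp and the 5 strongest distal ones, the 8 genes with most summits, and the strongest promoter-bound members of each other list. The EcR values were added after they were seen. For 7 list members a current symbol replaced the older one.

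The GC-matched background, the single-flank tests and the coding exon share were added after seeing the data. Background windows lay on a grid of 50 bp, over 1000 bp from any reproducible summit. They were matched to each summit on promoter class and GC content within 100 bp, in bins of 2 percentage points, with 200 draws. The alternatives tried were a stricter list, leaving out each replicate, other promoter widths, window sizes, flanks, elements, backgrounds and list tests.

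The statistics were tested on simulated data. For the promoter share, 5357 simulated summits with a planted share of 55.9% gave 56.0%. For the RORE, 5357 summits with a planted share of 5.07%, above the 1.29% observed, gave 5.08%, and 4% of 100 sets without effect were called. Those summits were placed at random and lacked the low GC content of the real ones. The rate therefore does not cover calls that base composition would give against the flanks. With GC-matched windows and no effect, 200 sets of 5357 windows gave a median RORE ratio of 1, with 95% of ratios from 0.627 to 1.65, and the coding exon ratio was 0.988. For the gene lists, over 13945 simulated genes all 20 planted lists and 2 of 200 unchanged ones were called. For lists of long genes without an effect of their own, Fisher's exact test called 32 of 50 over 13945 simulated genes, and random lists matched on length called 0. For the promoter and distal signals, a planted log2 ratio of 0.25 over 5357 peaks gave 0.29. For the replicate sharing, a planted 70.4% over 5357 peaks gave 71.5%.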

Results

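The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying, with both sexes pooled. The flies carried a transgene for Hr3 with green fluorescent protein (GFP) fused to its C-terminus, and an antibody against GFP was used for the precipitation. Hr3, also called Hr46, is a nuclear receptor of the ecdysone response and the fly counterpart of the mammalian retinoic acid receptor-related orphan receptors (ROR). The labels give 1 group of 3 biological replicates and no second condition, so the binding sites are described and no groups are compared. The files hold peaks and not reads, so the sequencing depth is unknown. The relaxed lists, which keep weak peaks for the reproducibility analysis, held 25578, 27006 and 23582 peaks for replicates 1, 2 and 3 on the dm6 assembly. All peak signals are the authors' values.

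The authors' reproducible list held 5357 peaks on dm6, all on chromosome arms X, 2L, 2R, 3L, 3R and 4. Peak widths had a median of 460 bp, and signals ran from 105.4 to 3379 with a median of 182.4. The peaks were the 5357 strongest of the 23597 relaxed peaks called on the pooled replicates. Of these peaks, 361 overlapped the next peak, which left 4996 separate regions.

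The replicates shared most of their strongest peaks. Of the 5357 strongest peaks of a replicate, 82.3% ± 2.14 (SD, n = 3) overlapped by at least 1 bp a peak among the 5357 strongest of another replicate, against 3.26% after random placement. Replicates 2 and 3 shared 85.8% of the peaks of replicate 2, and replicates 1 and 3 shared 79.7% of the peaks of replicate 1. Across the 5257 reproducible peaks with a signal in all 3 replicates, Spearman's rho was 0.783, 0.789 and 0.840 for the 3 pairs. These correlations are across peaks, which are not independent replicates. Median signal at the reproducible peaks was 40.4, 81.2 and 68.6 in replicates 1, 2 and 3, so each replicate's signals were divided by its own median to give the relative signal used below. The relative signal of a peak had a median coefficient of variation of 15.9% over the replicates.

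The strongest peaks lay at the genes cbt, CG14100, Chro, CG11050, Ugalt, CG46321, px, Art3, CG8320 and Tcs5, named by the nearest transcription start site (TSS). The highest peak was at 2L from 480808 to 481373 in an intron of ush, 1387 bp upstream of the TSS of cbt, with a relative signal of 17.4 ± 1.35 (SD, n = 3). The peak 91 bp upstream of the TSS of CG14100, at 3L from 19590401 to 19590856, reached 15.7 ± 0.730 (SD, n = 3). At Chro, which encodes the chromosomal protein Chromator, the summit lay 84 bp downstream of the TSS at 3L from 22878670 to 22879130, with 12.3 ± 0.496 (SD, n = 3). The peak nearest to CG46321 lay inside the Hr3 gene itself, at 2R from 10219845 to 10220329, with 11.8 ± 1.40 (SD, n = 3). Of the 10 peaks, 7 were at promoters and 3 were intronic. None of them had a ROR response element within 100 bp of the summit.

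Promoters held 51.5% of the reproducible summits and coding exons held almost none. With a promoter defined as 500 bp on either side of a TSS, 2758 summits were at promoters, 3.79 times the 13.6% ± 0.481 (SD) of 1000 random placements. The p from this permutation of positions was 0.001, 1-sided, the smallest that the placements can give. The ratio was 2.42 against peaks drawn from the weaker part of the replicates' relaxed lists, 5.86 with promoters of 200 bp and 2.59 with 1000 bp, all called. The share among the strongest peaks of the replicates was 51.2% ± 1.30 (SD, n = 3). Promoter summits lay upstream of the nearest TSS in 84.9% of cases, at a median signed distance of -118 bp. Introns outside promoters held 33.3% of summits against 39.5% at random, and intergenic sequence held 13.2% against 27.2%.

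**Figure D1:**
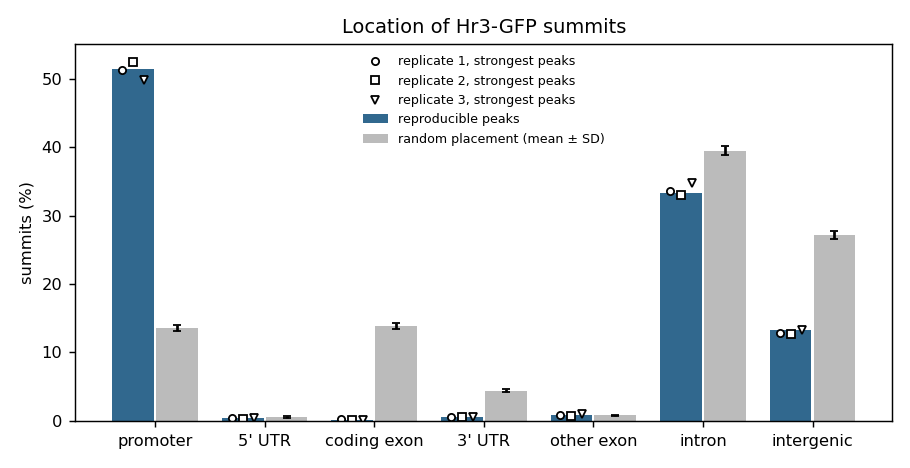
Share of summits (%) in each annotation class, for the 5357 reproducible peaks (blue bars), for random placements on the same arms (grey bars, mean ± SD of 100 placements) and for the strongest 5357 peaks of each replicate (open symbols). Promoters hold 51.5% of the summits against 13.5% at random, and coding exons outside promoters hold 0.131% against 13.9%.

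Coding exons were nearly devoid of summits. Counting promoters too, 18 of the 5357 summits lay in coding sequence, a share of 0.336% with a 95% exact binomial interval of 0.199% to 0.531%, against 17.1% at random. This result was singled out after its values were seen. At 500 bp from the summits the share in coding sequence was 19.2%. With the relaxed peaks of each replicate in 5 equal classes by signal, it was 0.321% ± 0.129 (SD, n = 3) in the strongest class and 10.5% ± 0.329 (SD, n = 3) in the weakest. The summits were also poor in G and C, with a mean GC content of 31.8% over 51 bp against 44.1% at 500 bp. Within 100 bp of the summits the mean was 34.1%. In background windows matched on that wider GC content and on promoter class, 6.35% of centres lay in coding exons.

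Chromosome 4, the small and largely heterochromatic autosome, carried fewer peaks than its length predicts. It held 21 summits where 53.9 were predicted, a ratio of 0.389, with an adjusted p of 2.9e-06 by the two-sided exact binomial test. The ratio in the replicates was 0.451 ± 0.0467 (SD, n = 3). Arm 2L held 1.08 times the predicted number, with an adjusted p of 0.0249 by the same exact test, a call that was lost in the higher-signal part of the list, with a ratio of 1.09, and when any 1 replicate was left out, with 1.06 to 1.07. Arms X, 2R, 3L and 3R had ratios of 1.03, 0.953, 1.01 and 0.978 and did not pass.

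The ROR response element (RORE), the sequence that ROR-type receptors are known to bind as monomers, was found at few summits, and more often there than in the flanks. A match to AWNTRGGTCA lay within 100 bp of 69 summits, 1.29% of the list with a 95% exact binomial interval of 1.00% to 1.63%, against 0.681% in windows 500 bp to each side. The ratio was 1.89 with a 95% bootstrap interval of 1.34 to 2.60 and an adjusted p of 0.00035 by the exact McNemar test over 19 elements. In the replicates the ratio was 2.08 ± 0.312 (SD, n = 3). The stricter element WAWNTAGGTCA had a ratio of 3.82. The exact McNemar test takes 1 flank per peak by a coin, and over 1000 coins its unadjusted p had a median of 0.00199, with a value at or below that of the reported coin in 99. The call was lost with windows of 50 or 200 bp, with ratios of 1.68 and 1.17. It was also lost with flanks at 1000 bp, the looser element NTRGGTCA or the weakest relaxed peaks as background, with 1.75, 1.11 and 1.57. At promoter summits the ratio was 2.07, with an adjusted p of 0.0436 by the exact McNemar test. At distal summits it was 1.78 and not called, with an adjusted p of 0.206 by the same test. Each of these p-values rests on 1 coin, and the 1000 coins were run for all summits only. Whether the call at promoters alone would hold with other coins is therefore unknown. The difference between the classes was not tested.

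A RORE lay within 50 bp of 32 summits, and of the 8 strongest of these peaks, 3 lay in ftz-f1 and Eip75B; whether this exceeds chance was not tested. The strongest was 145 bp upstream of Pomp, at 2L from 20787288 to 20787751, with a relative signal of 6.02 ± 0.742 (SD, n = 3). The next pair lay in introns of ftz-f1, a nuclear receptor gene of the ecdysone response, at 3L from 18759217 to 18759598 and from 18789380 to 18789791, with 4.79 ± 0.760 and 4.27 ± 1.48 (SD, n = 3). The first of these was nearest to the TSS of lncRNA:CR45938. An intronic peak of Eip75B, another ecdysone-induced nuclear receptor gene, at 3L from 17972410 to 17972664 reached 2.07 ± 0.328 (SD, n = 3). The remaining ones were intronic peaks of Prp16, of kdn and of beat-Ib near lncRNA:CR44867, and a peak at the promoter of lncRNA:CR44867. The 5 strongest over 500 bp from any TSS were those in ftz-f1, Prp16, beat-Ib and Eip75B.

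Several other elements had higher ratios to the flanks than the RORE, without a test of the differences. The DNA replication-related element (DRE), a core promoter sequence of housekeeping genes, was at 3.92% of summits, 8.57 times the flanks with an adjusted p of 1.9e-38 by the exact McNemar test. Motif 1, another such sequence, was at 1.46%, with a ratio of 9.18 and an adjusted p of 1.1e-15 by the same exact test. The core sequence of CTCF, an insulator protein, had a ratio of 4.81, and the core promoter sequences Ohler 7 and Ohler 6 had ratios of 3.21 and 6.33. DRE, Motif 1, Ohler 7 and Ohler 6 were raised at promoter summits, with ratios of 12.1, 11.4, 4.62 and 9.67. At distal summits they were not called, with 1.25, 2.00, 1.00 and 3.00. The CTCF core was raised in both, with ratios of 4.14 and 5.50. Su(Hw) had a ratio of 3.25 and the AT-rich Hox core TAATTA 1.92, and the hexamer RGGTCA, the core of many receptor sites, was below its flanks at 0.788. Against the weakest relaxed peaks of the same promoter class, where the RORE had 1.57, the ratios of DRE, Ohler 7, CTCF and the Hox core were 1.76, 1.97, 3.91 and 1.55, still called. Motif 1, Ohler 6, Su(Hw) and RGGTCA lost their calls there, with ratios of 1.05, 1.23, 1.13 and 0.874. In the higher-signal part of the list Ohler 6, Su(Hw) and RGGTCA were not called, with ratios of 3.43, 2.40 and 0.807. Su(Hw) also lost its call with windows of 200 bp or flanks at 1000 bp, with 2.17 and 2.36, and RGGTCA without replicate 2, with 0.838.

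The flank ratios of several elements did not hold when windows of the same GC content were used. Against those windows, a background chosen after seeing the data, the Hox core had a ratio of 1.06, Su(Hw) 1.04, Ohler 6 1.65 and the hexamer RGGTCA 0.988, and none of these was called. DRE, Motif 1, Ohler 7 and CTCF were called, with ratios of 2.88, 3.55, 4.84 and 8.56, and the RORE with 2.30. Those ratios are from 1 draw of windows, and against the mean of 200 draws the RORE had a ratio of 1.96. With summits resampled and set against each single draw in turn, 95% of the ratios lay from 1.23 to 3.85. The GAGA factor sequence GAGAGAG was below its flanks, with a ratio of 0.580, and above the GC-matched windows, with 2.05. Its ratio to the flanks was 0.441 and called at distal summits, and 0.828 and not called at promoter summits. It was not called with windows of 200 bp, with flanks at 1000 bp or against the weakest relaxed peaks, with ratios of 1.01, 0.751 and 0.870. Zelda and the CACGTG E-box were below their flanks, with ratios of 0.552 and 0.636, and were not called against the matched windows. Against the flanks Zelda was called at promoter summits, with 0.349, and not at distal ones, with 0.847. The E-box was called at both, with 0.695 and 0.557. In the higher-signal part of the list neither Zelda nor this E-box was called, with ratios of 0.620 and 0.772. Zelda also lost its call among peaks strongest in all 3 replicates, with windows of 50 bp and against the weakest relaxed peaks, with 0.615, 0.588 and 0.769. The E-box lost it without replicate 2, with 0.675, and kept it against the weakest relaxed peaks, with 0.705. Grainyhead, Ftz-f1, EcR/Usp, DR1, Caudal, the CATATG E-box and the reversed RORE had ratios of 0.318, 0.294, 1.00, 0, 1.09, 1.07 and 1.14 against the flanks and did not pass. Grainyhead and Ftz-f1 passed with the left flank alone, with adjusted exact p-values of 0.0170 and 0.0155, and with the right, with 0.00763 and 0.0361. At promoter summits they were below the flanks with adjusted exact p-values of 0.0328 and 0.00535, and Caudal was above them with a ratio of 1.54 and 0.000658. None of Grainyhead, Ftz-f1 and Caudal was called at distal summits, with ratios of 0.417, 0.667 and 0.829. Grainyhead also passed without replicate 1 or 2 and among peaks strongest in all 3 replicates, with ratios of 0.308, 0.412 and 0.364. Ftz-f1 also passed without replicate 3, with flanks at 1000 bp and with windows of 200 bp, with 0.214, 0.294 and 0.385. The CATATG E-box passed with windows of 200 bp, with 1.09. Against the GC-matched windows Grainyhead, Ftz-f1, Caudal and the CATATG E-box had ratios of 1.00, 0.625, 0.890 and 1.11 and were not called.

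**Figure D2:**
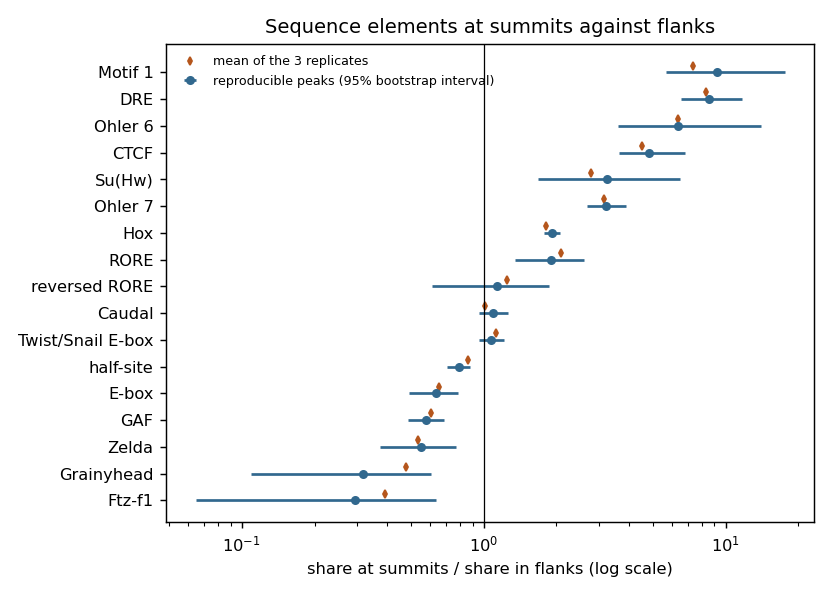
Ratio of the share of summits with each element to the share of flank windows with it (log scale). Circles are the 5357 reproducible peaks with 95% bootstrap intervals and diamonds the mean of the 3 replicates; EcR/Usp and DR1, with 2 and 0 matches, are left out. Motif 1 and DRE have ratios of 9.18 and 8.57, and the RORE 1.89.

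Promoter peaks were stronger than distal ones in all 3 replicates. The log2 ratio of their median signals was 0.26 ± 0.03 (SD, n = 3), and the permutation p across peaks was 1e-05 in each replicate, the smallest that 100000 permutations can give. Peaks with a RORE were not shown to differ in signal from those without. Their log2 ratio was 0.13 ± 0.11 (SD, n = 3), and permutation p-values in the replicates were 0.107, 0.960 and 0.165. At distal peaks it was 0.16 ± 0.21 (SD, n = 3), with a permutation p of 0.0095 in replicate 1, 0.935 in replicate 2 and 0.487 in replicate 3, unadjusted. With the remaining replicates combined, promoter peaks passed without replicate 3, with a log2 ratio of 0.51 and an unadjusted permutation p of 0.0178, and distal peaks without replicate 2, with 0.31 and 0.0364.

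Neither genes of the ecdysone response nor nuclear receptor genes passed the test for more bound promoters than other genes. Of 32 genes of the ecdysone cascade, 13 had a summit at a promoter, a share of 40.6% against 23.9% of the other protein-coding genes, with an adjusted p of 0.0962 by Fisher's exact test over 24 lists. These were Sox14, E23, vri, tai, Eip75B, Eip63F-1, usp, Hr78, dre4, ftz-f1, crol, EcR and Hr39. A further 9 had a summit in the gene or within 1 kb of it, namely Hr3, ImpL2, Smr, Hr4, br, Eip74EF, Hr38, Eip78C and Eip93F. The other 10, with no such summit, were Blimp-1, Cth, Cyp18a1, ImpE1, ImpE2, ImpE3, ImpL1, Kr-h1, MsrA and rig. Of 21 nuclear receptor genes, 10 were bound at a promoter, a share of 47.6% with an adjusted p of 0.0569 by Fisher's exact test. They were Hr96, ERR, Hnf4 and eg beside Eip75B, usp, Hr78, ftz-f1, EcR and Hr39. Hr3, Hr4, Hr51, Hr38, Eip78C and knrl were bound in the locus alone, and Hr83, dsf, kni, svp and tll had no summit. These lists share members, so they are not independent. Against random lists matched on the number of TSSs per gene, the adjusted permutation p-values were 0.764 for the ecdysone cascade and 0.396 for the nuclear receptors. In the higher-signal part of the peaks the nuclear receptors passed, with an adjusted p of 0.0343 by Fisher's exact test.

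The strongest peak in each of these genes or within 1 kb is given by relative signal (SD, n = 3), for the 12 genes that rank highest by the authors' signal. The intronic peak of Hr3 had 11.8 ± 1.40. The promoter peaks of Sox14 and of E23, which encodes an ecdysone-induced transporter, had 6.53 ± 1.19 and 6.22 ± 0.104. Intronic peaks of ftz-f1, ImpL2, Smr and Hr4 had 4.79 ± 0.760, 3.84 ± 0.258, 3.66 ± 0.567 and 3.20 ± 0.253. Promoter peaks of Hr96, ERR, vri, Hnf4 and tai had 3.03 ± 0.118, 2.55 ± 0.234, 2.56 ± 0.0860, 2.31 ± 0.361 and 2.24 ± 0.140. Of these, the ERR and tai peaks were nearest to the TSSs of other genes, Atg18a and CG9586. For EcR, the ecdysone receptor, an intronic peak had 2.24 ± 0.390 and the promoter peak 0.733 ± 0.142.

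Several of the same genes carried many summits. With 1 kb on either side, kirre had 20 summits, Eip75B 19, CG1677 17, sbb 16, ush 16, Hr4 13, Raf 12 and ftz-f1 12. Per 10 kb this was 0.505, 1.64, 1.34, 1.97, 2.41, 1.91, 2.38 and 2.28 in the same order, with the lowest value in kirre, the longest of them.

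Ribosomal protein, glycolysis and lipid metabolism genes were bound at promoters more often than other genes. Of 88 genes, 57 had a promoter summit, a share of 64.8% with a 95% exact interval of 53.9% to 74.7% and an adjusted p of 4.8e-15 by Fisher's exact test. RpS27, RpL34b and RpS20 had relative signals of 3.86 ± 0.167, 3.57 ± 0.286 and 3.03 ± 0.216 (SD, n = 3). Glycolysis genes were bound at 8 of 12 promoters, a share of 66.7% with a 95% exact interval of 34.9% to 90.1%, with an adjusted p of 0.0122 by the same exact test, and Eno and Gapdh2 had 3.85 ± 0.571 and 3.73 ± 0.286 (SD, n = 3). Lipid metabolism genes were bound at 9 of 17, with an adjusted exact p of 0.0435, and Lpin and bmm, which encode a phosphatidate phosphatase and a triglyceride lipase, had 2.73 ± 0.308 and 2.36 ± 0.332 (SD, n = 3). Against random lists matched on the number of TSSs per gene the glycolysis and lipid calls were lost, with adjusted permutation p-values of 0.309 and 0.323. The glycolysis call was also lost without replicate 2, at 50%, and the lipid call without replicate 1 or 3, at 47.1% in both.

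Cuticle protein and chemoreceptor families were bound at promoters less often than other genes. None of 70 genes of the Cpr cuticle protein family and none of 179 chemoreceptor genes had a promoter summit, with adjusted p-values of 5.7e-08 and 1.8e-20 by Fisher's exact test. The upper 95% exact bounds of their shares were 5.13% and 2.04%. Counts of promoter-bound genes in the other lists that did not pass were 7 of 13 for the circadian clock (sgg and vri among them), 7 of 18 for muscle (sls and Tm1), 6 of 19 for trachea (trh and dysf), 4 of 12 for fat body (Lpin and bmm) and 4 of 13 for germline (piwi and gcl). They were 4 of 22 for axon guidance and nerve cord (PlexA and Sema1a), 3 of 17 for neurons (elav and fne), 2 of 19 for neuroblasts (brat and grh), 2 of 17 for ecdysteroid synthesis and transport (shd and Npc1a), 2 of 10 for gut (Hnf4 and fkh) and 2 of 9 for apoptosis (hid and Drice). They were 1 of 25 for cuticle and chitin (Cht7), 1 of 22 for segmentation (bcd), 1 of 13 for hemocytes (ush), 1 of 10 for glia (moody), 1 of 8 for Hox genes (Dfd) and 0 of 9 for ecdysis hormones. The circadian clock passed without replicate 1, with an adjusted p of 0.0413 by Fisher's exact test. Cuticle and chitin genes passed as bound less often over whole gene loci, at 12%, with an adjusted permutation p of 0.0096 against length-matched lists. The elav promoter peak had a relative signal of 4.94 ± 0.0749 (SD, n = 3).

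**Figure D3:**
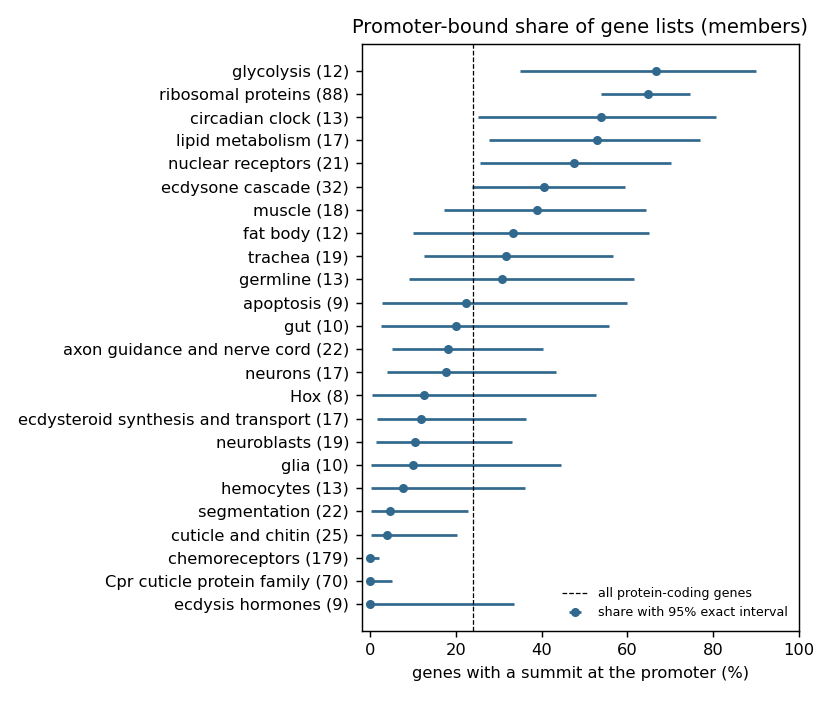
Share of genes (%) with a reproducible summit within 500 bp of a TSS, for each gene list (members in parentheses). Points are shares with 95% exact binomial intervals and the dashed line is the share of all protein-coding genes, 23.9%. Ribosomal protein genes lie at 64.8%, and chemoreceptor and Cpr genes at 0%.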

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

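The tests on GC-matched windows were chosen after the base composition of the summits was seen; the other tests were fixed earlier. In the pooled relaxed list, 286 peaks had the smallest q value of the list and were not in the reproducible list. All 5357 reproducible peaks had that same q value and were the strongest by signal. The 286 peaks therefore differ from them in signal and not in q.

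Summits in coding exons were few, 18 of 5357. If the low GC content of the summits were the whole cause, windows of the same GC content and promoter class would hold a like share, and 6.35% of their centres lay in coding exons, far above the upper bound of 0.531% for the summits. Composition may account for part of the deficit, since the share fell from 17.1% in random placements to 6.35% in matched windows. The match was on GC content within 100 bp and not on the lower GC content of the central 51 bp. Composition at that narrower scale was therefore not tested. Whether closed chromatin over coding exons explains the rest was not tested, and no biological explanation was tested.

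The excess of RORE matches at summits was set against a pair of technical explanations. Motif 1 shares the bases GGTCA with the RORE, but as searched it has C or T before them where the RORE has A or G. The same GGTCA therefore could not match both. With matches overlapping the shorter GGTCACA left out, 66 of the 69 summits kept a match, and the lower 95% bound of the ratio was 1.42. So few matches were removed that this test could hardly change the ratio, and no conclusion is drawn from it. For base composition, the reversed RORE had an interval of 0.611 to 1.86, which overlapped that of the RORE, as composition would predict; with 21 matches the interval holds both no excess and most of the RORE's, so this test alone leaves the question open. In GC-matched windows the lower bound of the RORE's ratio was 1.23. The matched draws held 21 to 53 matches against 69 at the summits. These values argue against GC content within 100 bp as the whole cause. The lower GC content of the central 51 bp was not matched, so composition at that scale was not tested. That the receptor itself binds these 69 sites remains a hypothesis; of the 5 settings fixed beforehand under which the call was lost, windows of 200 bp and the looser element left ratios of 1.17 and 1.11, and the others 1.57, 1.68 and 1.75, against 1.89.

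The Hr3 gene, the source of the tagged protein, held 6 reproducible summits, and 1 of the 10 strongest peaks. Extra copies of the region carried by the transgene could add reads there, and the relaxed summit counts within 10 kb of the gene, 24, 30 and 25 in replicates 1, 2 and 3, stood at percentiles 97.2, 99.2 and 98.8 of windows at other genes. The criterion set beforehand for this cause was not met, by 1 replicate, and neither was the criterion against it, so extra copies and binding of Hr3 to its own gene cannot be told apart. The control library and the extent of the transgene, which would decide it, were not analysed here.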

How the results depend on the processing

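The left-out replicates for arms, the single flanks, the GC-matched windows and all coding exon settings were chosen after seeing the data. The promoter excess, the promoter signal, the coding exon deficit and the calls of ribosomal protein, Cpr and chemoreceptor genes kept their direction and side of the threshold in all settings run. The reproducible list could not be rebuilt without a replicate, so peaks strongest in the remaining ones were used. Where not stated, the cause was not tested.

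Replicate sharing was 74.1% with summits within 100 bp, 75.2% with 50% reciprocal overlap, 85.2% with 0.5 times as many peaks, 79.9% with 1.5 times as many, and 80.5% to 85.6% without a replicate. The number of arms called fell from 2 to 1 in the higher-signal part of the list and without each replicate, where fewer peaks were tested. The RORE ratio was 1.68 with windows of 50 bp, 1.17 with 200 bp, 1.75 with flanks at 1000 bp, 1.11 with the looser element and 1.57 against the weakest relaxed peaks, none of them called, and 1.90 to 2.12 without a replicate. GAGAGAG turned to 1.01 with windows of 200 bp and to 2.05 against GC-matched windows, where Zelda turned to 1.11 and the CACGTG E-box to 1.20.

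In the higher-signal part, nuclear receptors were called at 38.1% and lipid metabolism was not, at 29.4%. Lipid metabolism also lost its call with promoters of 200 bp, at 23.5%, by locus, at 70.6%, against lists matched on TSSs, at 52.9%, and without replicate 1 or 3, over sets at 47.1% to 52.9%, the highest of which, without replicate 2, was called. Glycolysis lost it among peaks strongest in all replicates, at 50%, by locus, at 75%, against matched lists, at 66.7%, and without replicate 2, at 50% to 58.3% over the sets. Matching on TSSs left 3 of the 5 lists called.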

Other observations

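All tests in this part were chosen after the data were seen. Short sequences of 8 bases were compared between the summits and 1 draw of GC-matched windows, by Fisher's exact test, 1-sided, with Bonferroni adjustment. The smallest p was that of CACTGTGC, at 4.11% of the 5357 summits against 0.579% of windows, with an adjusted p of 8.3e-33 by the exact test over 32893 sequences. The ratio was higher for CAGCCCTG, at 94 summits against 6 windows, than for CACTGTGC, at 220 against 31. CACTGTGC was raised in both classes, at 3.41% of promoter summits against 0.580% of windows and at 4.85% of distal summits against 0.577%. The sequences with the smallest p differed between promoter and distal summits. At promoters, ATCGATAG, which overlaps the DRE, was at 7.47% of summits against 1.78% of windows. CAGCCCTG, which matches the inner part of the Ohler 7 sequence, was at 3.05% against 0.181%. At distal summits CACTGAGA was at 6.16% against 0.654%, CAGTGCAC at 4.77% against 0.423% and GAGAGAAA at 5.93% against 0.923%. The factors that bind these sequences were not tested.

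With the reproducible peaks in 5 classes from weakest to strongest, the promoter share was 43.8%, 45.3%, 49.5%, 53.7% and 65.1%. In the same order the DRE was at 5.13%, 4.20%, 3.83%, 4.20% and 2.24% of summits, and Motif 1 at 1.49%, 2.24%, 1.49%, 1.31% and 0.746%. Neither fell at every step, but both were lowest in the strongest class, where the promoter share was highest. The RORE was at 0.84% of summits and 0.84% of flank windows in the weakest class, so it had no excess there. In the strongest class it was at 1.49% against 0.466%. In each class between these, its share at summits was also above that in the flanks. The RORE shares rest on 69 summits with a match over all 5 classes, and the flank share was also lower in the strongest class than in the weakest. Peaks with a RORE were not shown to differ in signal from those without. The differences between classes were not tested.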
